A study of Lutjanus campechanus with 11 samples.

How the data were processed

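Spleen RNA of juvenile red snapper (Lutjanus campechanus) was measured by RNA sequencing in 11 libraries. Per the labels' protocols, RNA was purified with Qiagen RNeasy kits and polyadenylated transcripts were made into strand-marking Illumina TruSeq libraries. The submitters' processing notes name CASAVA, which calls and demultiplexes bases, and FastQC, which checks read quality. The mapper, the counting rule, the reference genome and its annotation are not given in the sources used here. Whether the reference was that of red snapper or of another species is thus not known. With a reference of another species, missing rows, absent reads and low levels could also reflect reads that failed to map.

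Per the file headers, each deposited table lists an expression value, TPM and RPKM for every gene, with a link to an NCBI gene record. The species of these gene records was not checked. The deposited expression values were whole numbers that summed to different totals in each library, and were used as gene read counts. The deposited TPM and RPKM values were made by the authors from the same reads and were not tested here. The header does not say whether reads mapping to several places were counted, so genes with near-identical copies are uncertain. All 11 tables held the same 23430 rows, of which 11598 carried a gene symbol and 11832 only a locus number. The files pair a locus number with no product name, so only symbols could be matched to gene lists. 6320 rows had no read in any library.

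Groups were taken from the sample titles: control (n = 2), oil (n = 3), pathogen (n = 3) and oil and pathogen (n = 3). The series describes spleens taken from exposed fish, but the labels do not say how many fish stand behind one library, so p-values measure the spread between these libraries. Counts were compared within groups by a chi-square test, and no 2 libraries of a group were alike within sampling noise.

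Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with too few reads for the group sizes were removed by filterByExpr, which left 11374 genes. Normalization factors came from the trimmed mean of M-values (TMM). One model with a mean per group was fitted to all 11 libraries, because controls had only 2. Contrasts were tested with the two-sided quasi-likelihood F test with robust dispersion, and p-values were adjusted by Benjamini-Hochberg over all genes at 0.05. The SE printed with a log2 fold change was back-calculated, as its absolute value divided by the square root of the F statistic. A fold change smaller than its SE thus only restates a small F. The 8 contrasts were oil, pathogen and both against control, both against each single exposure, the interaction, and the oil and pathogen effects averaged over the other factor. Levels are CPM, the counts edgeR scales by library total and TMM factor, as mean ± SD. The common biological coefficient of variation was 0.61.

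A total of 23 gene lists with 953 symbols was fixed before the data were examined, and 490 of those symbols had a row. Lists were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a contrast. Members were also adjusted over the list alone. Some genes stand on 2 lists, such as c8a on the liver and acute-phase lists and lyz on the acute-phase and neutrophil lists. A list score per library is the mean log2 deviation of its members from their mean over all libraries. The lists cover aryl hydrocarbon receptor, phase II, pro-inflammatory, pattern recognition, acute-phase, interferon, antigen presentation, B cell, T cell, neutrophil and macrophage, erythroid, thrombocyte, exocrine pancreas, liver, muscle, heat shock, cell cycle, apoptosis, sterol, glucocorticoid, circadian, oxidative phosphorylation and ribosomal protein genes.

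The rule for named genes, fixed together with the lists, took exposure indicators (among them cyp1a, cyp1b1, cyp1c1, ahrr, tiparp, hmox1, il1b, il8, tnf, il6, hamp, saa, c3, c7, lyz, nos2, mmp9, mmp13 and irf1), the largest changes past the threshold, and up to 4 list members past it. Where fewer than 5 genes passed, the 5 smallest p-values were to be given as not past the threshold. No gene passed, so the 5 smallest p among rows with a symbol are named. This limit to symbols was added after the values were seen. The 4 numbered loci, irg1 and gp91phox outside the rule, and the genes given as list examples, were chosen after their values were seen. No row was named cyp1a, cyp1b1, cyp1c1, tnf, il6, saa, c3 or nos2, and mmp13 and tnfa, another indicator, had rows with too few reads to be tested.

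Other settings fixed at the same stage were DESeq2 size factors, no count filter, the DESeq2 1.42.0 Wald test, only the 2 groups compared, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and limma's fry. The DESeq2 test was run on all 23430 rows, without filterByExpr and with its own filter on low counts. Its p-values were thus adjusted over other genes than those of edgeR, and the numbers called are not directly comparable. Chosen after the data were seen were limma-voom with sample quality weights, leaving out both pathogen 1 and pathogen 3, DESeq2 without pathogen 3, and list tests without single libraries. The steps were tested on simulated data drawn from the real means, library sizes and dispersions. For 50 genes per size changed in oil against control (11014 genes tested), the test recovered 0% at 2-fold, 2% at 4-fold, 18% at 8-fold and 52% at 16-fold. For both against pathogen (11012 genes) it recovered 2%, 10%, 46% and 62%, and for the average oil effect (11030 genes) 2%, 22%, 72% and 86%. A simulated 2-fold rise of the cell cycle list was called in each of these comparisons with the preset correlation, at adjusted p = 7.39e-11, 3.31e-13 and 1.89e-18, and with an estimated correlation, at 0.00165, 0.000866 and 0.000283. Simulated genes were drawn independently, while the real cell cycle list had an estimated correlation of 0.303, so these list results do not carry over. For oil against control 4.6% of unchanged simulated genes had an unadjusted p under 0.05, against 53 of 11374 real genes. The recovery shares therefore need not hold for the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

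Library totals ran from 3004929 to 7048307 counts. At these depths, 3 reads, the upper limit that a count of 0 allows, correspond to between 0.411 CPM in oil 2 and 2.19 CPM in pathogen 3. Such limits cover counting error only, and not reads that failed to map to a reference whose species is not known.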

Results

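The transcriptome of the spleen, a main immune and blood-filtering organ of fish, was compared in juvenile red snapper after exposure to crude oil, a bacterial pathogen or both. Oil was given for 8 days as a high-energy water-accommodated fraction of Macondo well oil, an oil-in-water mixture made by vigorous stirring. The pathogen was Vibrio anguillarum, a marine bacterium that causes vibriosis, given in a bath of 750000 CFU/mL for 1 h, 24 h before sampling. Labelled oil concentrations were 0.563 μg/L for controls (n = 2), 0.736 for pathogen (n = 3), 17.084 for oil (n = 3) and 15.799 for oil and pathogen (n = 3). All fish were held at a salinity of 30 ppt and 23 °C. Total gene counts were 5336045 and 4926786 in the controls, 3626380, 7048307 and 3879939 with oil, 5828841, 4743448 and 4307503 with pathogen, and 3615605, 3527527 and 3004929 with both. Levels are normalized counts (CPM).

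Markers of other tissues differed between libraries. Exocrine pancreas genes, such as the digestive enzyme genes cpa1 and cela1, held 2.80% of counts in pathogen 3, 0.836% in control 2 and 0.492% in oil 2, against 0.0156% in oil and pathogen 3. Liver genes, such as the prothrombin gene f2 and the plasminogen gene plg, held 1.28% in pathogen 3 and 0.154% in oil 3, and at most 0.0324% in the other libraries. The 10 most abundant genes of pathogen 3 took 52.4% of its counts, and its median correlation with the others was 0.61 on log2 CPM, against 0.82 to 0.92 for the other 10 libraries. Pathogen 1 had the fewest genes with a read, 10699, and carried transcripts of the islet hormones insulin (ins, 159.4 CPM) and glucagon (gcg, 95.97 CPM). The TMM factors of these libraries were 0.318 for pathogen 3 and 0.49 for pathogen 1, against 1.01 to 1.73 elsewhere. Fold changes and list scores below depend on these factors, and list results were not computed without a factor. The gene list calls below used a preset correlation between genes and were all lost with an estimated one. Of 100 groupings of the same libraries, the real one included, 46 gave at least as many list calls for the average oil effect and 75 for the average pathogen effect.

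**Figure D1:**
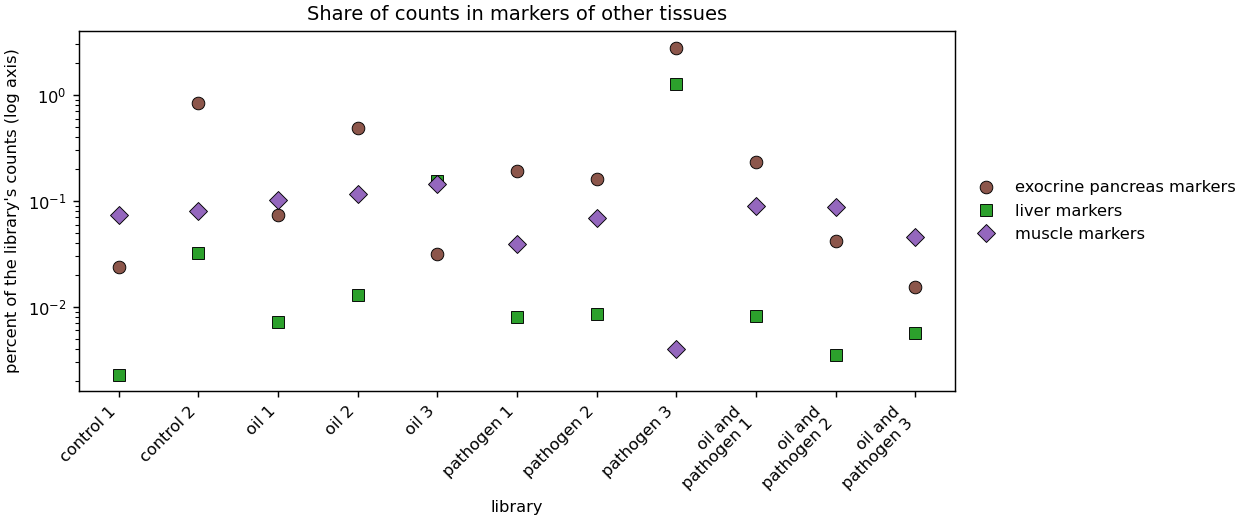
Percent of each library's counts (log axis) in the fixed lists of exocrine pancreas (circles), liver (squares) and muscle (diamonds) markers, with the 11 libraries along the x axis. Pathogen 3 holds the largest pancreas and liver shares, 2.80% and 1.28%.

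The exposure indicators with enough reads were 10 genes. The aryl hydrocarbon receptor repressor ahrr (gene ID 654288), a target and feedback inhibitor of the receptor that senses planar aromatic hydrocarbons, averaged 1.59 ± 2.25 CPM in controls, 2.26 ± 0.475 with oil, 14.6 ± 18.2 with pathogen and 28.9 ± 13 with both. Tiparp (gene ID 101080203), another target of that receptor, averaged 44.3 ± 9.29, 31.0 ± 5.19, 85.7 ± 71.1 and 89.9 ± 41.1 CPM in the same order. The neutrophil-attracting chemokine il8 (gene ID 445923) averaged 0.756 ± 0.0678, 0.729 ± 0.117, 1.60 ± 0.632 and 19.8 ± 30.5 CPM. The cytokine gene il1b averaged 1.08 ± 1.03, 1.10 ± 0.997, 0 and 20.3 ± 27.1 CPM, and the gelatinase gene mmp9 7.31 ± 4.93, 9.18 ± 3.15, 2.00 ± 1.43 and 132 ± 183 CPM. Hepcidin (hamp), an iron-regulating and antimicrobial peptide, averaged 7.70 ± 5.88, 10.7 ± 12.6, 57.1 ± 90.5 and 77.4 CPM, the last from libraries at 26.9, 6.67 and 198.5 CPM. Heme oxygenase 1 (hmox1) averaged 17.4 ± 7.81, 13.3 ± 2.63, 14.7 ± 9.0 and 22.0 ± 19.1 CPM, and the transcription factor irf1 34.3 ± 4.24, 33.8 ± 11.5, 23.8 ± 17.3 and 39.4 ± 19.1 CPM. The complement gene c7 averaged 0.502 ± 0.710, 0.581 ± 0.598, 31.4 ± 54.4 and 9.80 ± 16.8 CPM, and lysozyme (lyz) 21.9 ± 31.0, 67.3 ± 114, 139 ± 143 and 42.3 ± 37.6 CPM.

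**Figure D2:**
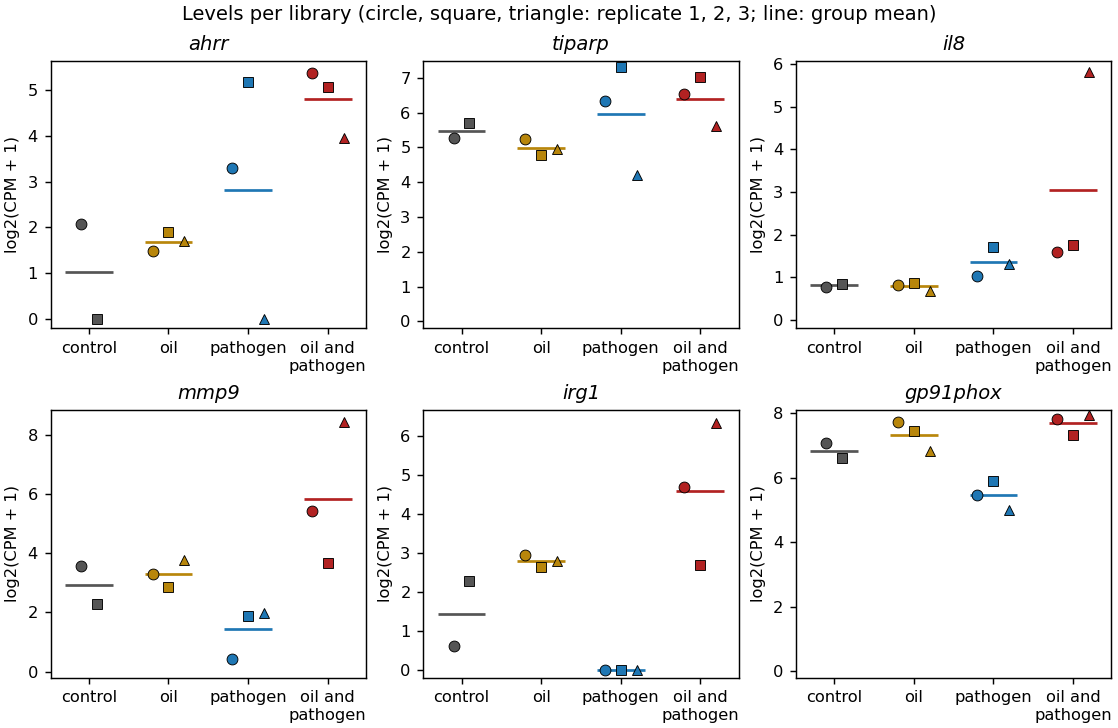
Levels of 6 genes in each library as log2(CPM + 1), by exposure group on the x axis; symbols mark replicates and lines the group means of the plotted values. Pathogen 3 has 0 reads of ahrr, all 3 pathogen libraries have 0 reads of irg1, and oil and pathogen 3 has the highest il8, mmp9 and irg1.

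The comparison of oil with control asked what 8 days of oil did without the pathogen. Cell cycle genes were higher with oil in 39 of 43 members, with a median log2 fold change of 0.40 (camera adjusted p = 9.88e-06). Adjusted p = 0.95 with an estimated correlation, and 0.414 without control 2. The replication gene gins2 averaged 6.01 ± 1.66 CPM with oil (n = 3) and 1.83 ± 1.17 in controls (n = 2), and the helicase gene mcm2 81.9 ± 19.6 against 45.02 ± 7.14. Cytoplasmic ribosomal protein genes were lower in 62 of 63 members, with a median of -0.33 (camera adjusted p = 8.37e-10), adjusted p = 0.95 with an estimated correlation and 0.717 without oil 3. Ahrr differed from controls by a log2 fold change of 0.49 (SE 1.40) and tiparp by -0.51 (SE 0.68), each smaller than its SE, which comes from the fit to all 11 libraries. The value of ahrr turned to -0.49 without control 2, and without control 1, which leaves a control with 0 reads, the fitted value was 6.43. The other indicators had 1.63 for lyz, 0.49 for hamp, 0.36 for c7, 0.33 for mmp9, 0.13 for il1b, -0.02 for irf1, -0.05 for il8 and -0.38 for hmox1, each smaller than its SE and at an edgeR adjusted p of 1. Without oil 2 lyz had -3.56 and hamp -1.16, and without control 1 c7 had -0.65 and il1b -0.61. The smallest p among named genes belonged to tldc1 (log2 fold change 2.24, SE 0.71), zyg11b (2.16, SE 0.70), the myosin heavy chain gene myhm2126-1, with 3.41 ± 2.90 CPM against 0.0885 ± 0.125, rabgap1 (1.48, SE 0.49) and the pentose phosphate gene pgls (1.44, SE 0.49). All had an edgeR adjusted p of 1. The edgeR test called 0 of 11374 genes and gave 53 at an unadjusted p under 0.05, where 569 were expected by chance. DESeq2 and voom with quality weights called 0 as well. The count at an unadjusted p under 0.05 was 185 with only the 2 groups compared and 258 with voom. Each lay below 569, so the p-values of this comparison cannot be taken as calibrated. The edgeR counts for both against control (423), both against oil (288) and the interaction (433), given below, also lay under 569. The same caution holds for them.

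In the pathogen comparison with control, which asked for the spleen response a day after bathing in bacteria, oxidative phosphorylation genes were higher in 23 of 23 members (median log2 fold change 1.07, camera adjusted p = 8.37e-11). Adjusted p = 0.64 with an estimated correlation. The complex I gene ndufb8 averaged 58.3 ± 20.2 CPM with pathogen (n = 3) and 23.2 ± 2.44 in controls (n = 2). Oxidative phosphorylation scores were 1.02, -0.10 and 0.99 with pathogen and -0.08 and -0.53 in controls. The high scores were those of pathogen 1 and pathogen 3, whose TMM factors were 0.49 and 0.318, against 1.012 in pathogen 2. How much of the list rises in this comparison these factors make up was not tested. Ribosomal protein genes were higher in 63 of 63 (median 0.69, adjusted p = 5.32e-10) and phase II and oxidative stress genes in 18 of 22 (median 0.50, adjusted p = 0.000558), both with adjusted p = 0.64 with an estimated correlation. On the phase II list the superoxide dismutase gene sod1 averaged 108 ± 60.9 CPM against 25.0 ± 12.9. Erythroid genes were higher in 18 of 22 (adjusted p = 0.0393, and 0.69 with an estimated correlation), a call lost without control 1 (0.0518), control 2 (0.183), pathogen 1 (0.718) or pathogen 2 (0.249). T cell markers were lower in 12 of 13 (median -0.84, adjusted p = 0.00539), B cell markers in 9 of 12 (adjusted p = 0.0156) and pattern recognition genes in 10 of 15 (adjusted p = 0.0393), each at adjusted p = 0.64 with an estimated correlation. Without pathogen 3 these adjusted p-values were 0.68, 0.589 and 0.653, and without control 1 the last pair gave 0.0956 and 0.152. With the replicate number as a block the T cell (0.0904), B cell (0.0715) and pattern recognition (0.118) calls were lost, so that 0 lists were called lower. Without both pathogen 1 and pathogen 3 the ribosomal list pointed down (adjusted p = 0.925), and the oxidative phosphorylation, phase II and T cell lists had 0.402. Mean and test of the pattern recognition list differed in sign, with a mean log2 fold change of 0.11 and a median of -0.73.

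Liver markers were higher with pathogen in 15 of 15 members (camera adjusted p = 0.000175), acute-phase and complement genes in 17 of 17 (adjusted p = 0.00146) and exocrine pancreas markers in 5 of 5 (adjusted p = 0.00477). Each had adjusted p = 0.64 with an estimated correlation. The values rested on pathogen 3: without it the adjusted p was 0.72 for liver, 0.905 for acute-phase genes, which then pointed down, and 0.349 for pancreas, which was also lost without control 1 (0.665). The acute-phase call was lost with the block too (0.0673). The fibrinogen gene fga, for example, had 1155 CPM in pathogen 3 and 0 in pathogen 1 and pathogen 2. The log2 fold change of ahrr was 3.20 (SE 1.48, edgeR adjusted p = 0.757) and that of tiparp 0.96 (SE 0.70, adjusted p = 0.783). The other indicators had 5.91 for c7 (SE 3.73), 2.87 for hamp (SE 2.15), 2.67 for lyz (SE 3.22), 1.11 for il8 (SE 1.35), -0.20 for hmox1 (SE 0.72), -0.51 for irf1 (SE 0.66) and -1.90 for mmp9 (SE 1.26), at adjusted p-values from 0.771 to 0.962. Without pathogen 3 hamp had -0.68 and lyz 1.58. C7 had 0 reads in pathogen 1 and pathogen 2, and il1b had 0 in the 3 pathogen libraries. The named genes with the smallest p were the meiosis gene mnd1, with 0 reads in the 3 pathogen libraries and 2.49 ± 1.02 CPM in controls, the focal adhesion gene pxn (log2 fold change -3.16, SE 0.76), tldc1 (2.87, SE 0.73), fam20c2 with 14.7 ± 19.6 CPM against 0.10 ± 0.142, and the receptor kinase gene mst1r (-3.71, SE 0.97), all at adjusted p = 0.757. The edgeR test called 0 genes, with 670 at an unadjusted p under 0.05, DESeq2 called 22 (12 without pathogen 3) and voom with quality weights 0. The count of 670 was 1970 without pathogen 2, 878 without pathogen 1, 708 without pathogen 3, 117 with only the 2 groups and 198 with voom.

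The combined exposure against control set fish given oil and pathogen together against fish given neither. Pro-inflammatory cytokine, chemokine and NF-kB genes were higher in 15 of 20 members (median log2 fold change 0.59, camera adjusted p = 0.00728) and neutrophil and macrophage markers in 14 of 17 (median 0.68, adjusted p = 0.00728), while T cell and NK cell markers were lower in 13 of 13 (median -1.03, adjusted p = 0.000102). Heat shock and unfolded protein response genes were higher in 26 of 31 (median 0.76, adjusted p = 1.29e-05), erythroid and heme genes in 19 of 22 (median 0.86, adjusted p = 0.00027) and cell cycle genes in 32 of 43 (median 0.53, adjusted p = 0.00344). Ribosomal protein genes were lower in 62 of 63 (median -0.78, adjusted p = 1.87e-18), with scores of -0.87, -0.06 and -1.13 in the libraries with both exposures and 0.36 and 0.01 in controls. On the T cell list oil and pathogen 3 stood apart at -2.0, while oil and pathogen 1 and 2 scored 0.08 and 0.35 and the controls 0.95 and 0.69. All 7 lists had adjusted p = 0.82 with an estimated correlation. Without oil and pathogen 3 the pro-inflammatory list had adjusted p = 0.323, without control 2 the neutrophil list had 0.112 and the cell cycle list 0.508, and without oil and pathogen 2 the cell cycle list had 0.44. The transferrin receptor tfrc averaged 100.2 ± 54.0 CPM (n = 3) against 36.8 ± 2.23 (n = 2), the stress-response gene manf 31.4 ± 26.9 against 2.70 ± 2.68, and the T cell kinase gene lck 33.1 ± 24.3 against 67.9 ± 17.9.

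Among indicators, log2 fold changes for the combined exposure against control were 4.67 for il8 (SE 1.41), 4.22 for il1b (SE 1.64), 4.17 for mmp9 (SE 1.36) and 4.13 for ahrr (SE 1.54), all at an edgeR adjusted p of 0.998. Il8 read 55.1 CPM in oil and pathogen 3 and 2.03 and 2.38 CPM in the other 2 libraries of the group, whereas ahrr was 39.9, 32.2 and 14.5 CPM against 3.19 and 0 in controls. Without oil and pathogen 3 the log2 fold changes were 1.51 for il8, 2.13 for il1b, 1.86 for mmp9, 2.81 for irg1, 1.14 for hamp and 4.45 for ahrr. That library also held 139 of the group's c7 reads, against 1 and 0 in the others. The other indicators had 4.26 for c7 (SE 3.53), 3.33 for hamp (SE 2.19), 1.02 for tiparp (SE 0.70), 0.95 for lyz (SE 2.98), 0.34 for hmox1 (SE 0.72) and 0.20 for irf1 (SE 0.66). The immune-responsive gene irg1 (gene ID 101063714), which makes itaconate in activated macrophages, had a log2 fold change of 4.08 (SE 1.18). The tight junction gene cldn5b averaged 0.511 ± 0.319 CPM against 6.30 ± 0.10 (log2 fold change -3.52, SE 0.82), and the other small p-values were those of pgls (1.92, SE 0.50), the transporter gene abcc5 (1.78, SE 0.48), the blood progenitor factor gata2 (-2.49, SE 0.68) and mboat7 (2.76, SE 0.75). With edgeR 0 genes were called, with 423 at an unadjusted p under 0.05, against 12 by DESeq2 (45 without pathogen 3) and 4 by voom with quality weights.

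**Figure D3:**
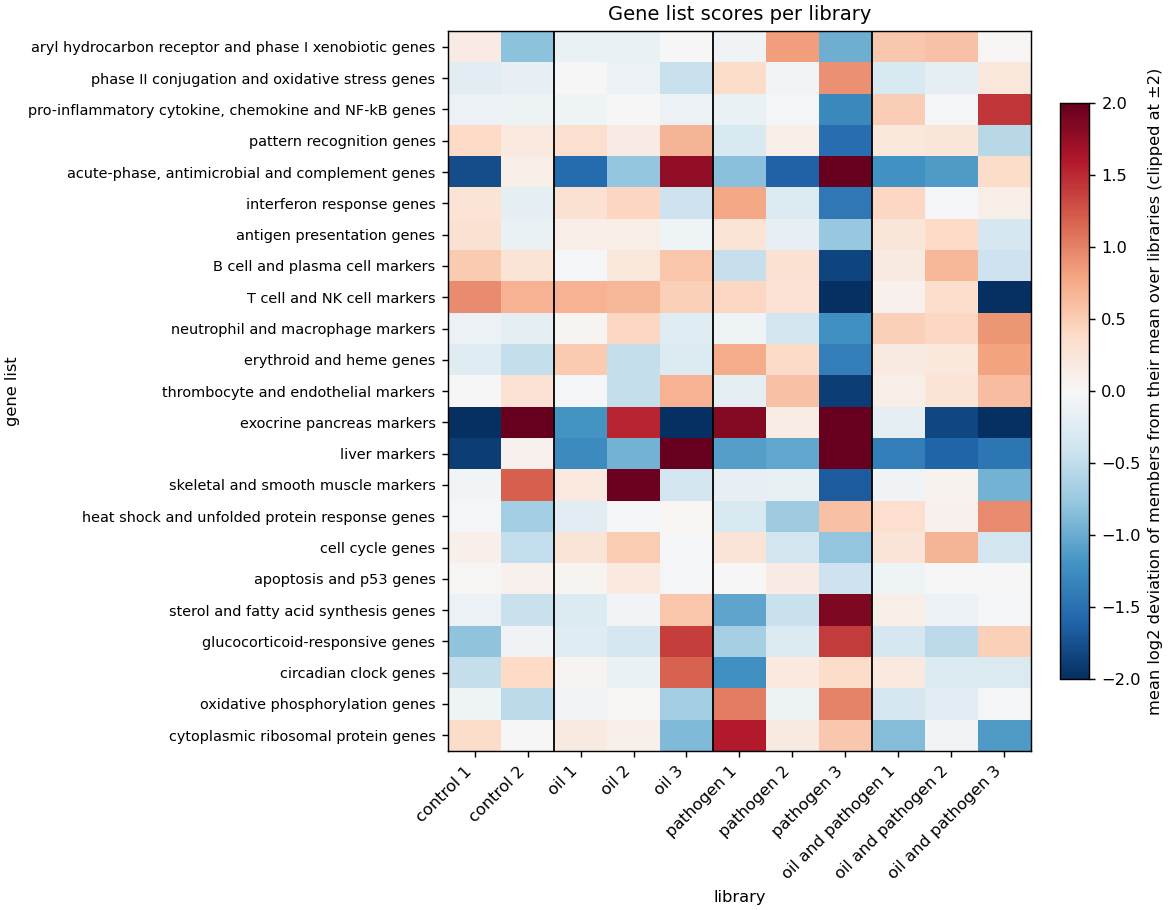
Score of each fixed gene list (rows) in each library (columns), the mean log2 deviation of members from their mean over the libraries, clipped at ±2 in colour. Pathogen 3 scores 7.87 for liver and -2.63 for T cell markers, and oil and pathogen 3 scores 1.43 for pro-inflammatory genes and -2.0 for T cell markers.

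Oil given together with the pathogen was compared with the pathogen alone, 3 libraries against 3. Ribosomal protein genes were lower in 62 of 63 members (median log2 fold change -1.53, camera adjusted p = 1.63e-35), and 60 of the 63 passed when adjusted over the list alone, against 0 over all genes. Oxidative phosphorylation genes were lower in 22 of 23 (median -1.03, adjusted p = 3.52e-08, 3 past the threshold adjusted over the list alone) and phase II genes in 15 of 22 (median -0.66, adjusted p = 0.00571, 7 past it over the list alone). The ribosomal gene rpl23a averaged 2540 ± 1050 CPM with both and 10670 ± 2720 with pathogen. Ribosomal scores were 1.58, 0.18 and 0.54 with pathogen and -0.87, -0.06 and -1.13 with both. TMM factors, in the same order of libraries, were 0.49, 1.012 and 0.318 against 1.636, 1.19 and 1.583. How much of the fall these factors make up was not tested. Neutrophil and macrophage markers were higher in 14 of 17 (median 0.63, adjusted p = 0.00334, mmp9 past the threshold adjusted over the list alone) and pro-inflammatory genes in 17 of 20 (median 1.14, adjusted p = 0.00496, il1b past it). Liver markers were lower in 14 of 15 (adjusted p = 0.000167), acute-phase genes in 14 of 17 (adjusted p = 0.00733) and pancreas markers in 5 of 5 (adjusted p = 0.000205). With an estimated correlation the adjusted p was 0.60 for the ribosomal, oxidative phosphorylation, phase II, neutrophil and pancreas lists, 0.74 for the pro-inflammatory and liver lists and 0.86 for the acute-phase list. Without pathogen 3 the adjusted p was 0.302 for pro-inflammatory, 0.0843 for neutrophil and 0.375 for liver genes, and acute-phase genes pointed up at 0.864. Without pathogen 1 phase II genes had 0.0552, and without oil and pathogen 2 acute-phase genes had 0.0649. Without both pathogen 1 and pathogen 3 the calls of phase II (0.723), oxidative phosphorylation (0.723), pancreas (0.249) and liver genes (0.854) were lost, and acute-phase genes pointed up (0.253). Of the apoptosis list, 2 of 18 members passed when adjusted over the list alone, but the list did not (adjusted p = 0.528). The smallest of these p-values was that of the p53-responsive gene rps27l, with 27.0 ± 6.14 CPM with both and 98.1 ± 35.1 with pathogen.

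The gene with the smallest p in this comparison was gp91phox, the catalytic subunit of the phagocyte NADPH oxidase, with 210.1 ± 45 CPM with both against 44.3 ± 14.3 with pathogen (log2 fold change 2.24, SE 0.40, edgeR adjusted p = 0.271). Irg1 had 0 reads in all 3 pathogen libraries, so its mean of 36.8 ± 38.7 CPM with both was at least 28.6-fold higher, taking 3 reads per library as the limit. On the same basis il1b was at least 15.7-fold higher. These limits rested on single libraries: without oil and pathogen 3 they were 11.8-fold for irg1 and 3.67-fold for il1b, and without pathogen 3, which has the highest floor, 43.96-fold and 24.2-fold. Cldn5b (log2 fold change -4.30, SE 0.81) and the mitochondrial gene romo1 (-2.71, SE 0.51) were lower, and lrrc32 had 6.32 ± 2.96 CPM with both and 1 read in the pathogen libraries together. Mmp9 had a log2 fold change of 6.06 (SE 1.30) and il8 one of 3.56 (SE 1.14, adjusted p = 0.276), which were 3.75 and 0.41 without oil and pathogen 3. DESeq2 called gp91phox (adjusted p = 1.2e-05), irg1 (9.9e-06), mmp9 (1.2e-05), il1b (0.000743), cldn5b (0.000184), romo1 (0.00015) and lrrc32 (0.00542). The other indicators had 0.93 for ahrr (SE 1.12), 0.70 for irf1 (SE 0.59), 0.55 for hmox1 (SE 0.65), 0.46 for hamp (SE 1.69), 0.06 for tiparp (SE 0.61), -1.64 for c7 (SE 2.45) and -1.72 for lyz (SE 2.65), at adjusted p-values from 0.654 to 0.978. Hamp had -1.74 without oil and pathogen 3 and 4.02 without pathogen 3 (adjusted p = 0.348), so its direction rested on single libraries. EdgeR called 0 genes and gave 1509 at an unadjusted p under 0.05, of which 910 were lower. That count ran from 780 without oil and pathogen 3 to 2504 without pathogen 2, and was 757 with only the 2 groups and 808 with voom. DESeq2 called 356 (88 higher, 268 lower) and, without pathogen 3, 271 (138 higher, 133 lower). Voom with quality weights called 0. Without pathogen 2 edgeR called 1.

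The pathogen effect within oil-exposed fish was read from both exposures against oil, again 3 against 3. Pro-inflammatory genes were higher in 15 of 20 members (median log2 fold change 0.59, camera adjusted p = 0.000499), and il8 passed when adjusted over the list alone. Heat shock genes were higher in 26 of 31 (median 0.54, adjusted p = 2.96e-05), neutrophil markers in 12 of 17 (median 0.31, adjusted p = 0.00724) and erythroid genes in 17 of 22 (median 0.70, adjusted p = 0.00228). T cell markers were lower in 12 of 13 (median -1.01, adjusted p = 5.35e-05) and ribosomal protein genes in 62 of 63 (median -0.45, adjusted p = 2.06e-08). With an estimated correlation the adjusted p was 0.92 or 0.93 for all 6 lists. The T cell call was lost without oil and pathogen 3 (0.0766), which scored -2.0 on that list, the neutrophil call without oil 3 (0.139), and the erythroid call without oil 2 (0.0867), oil 3 (0.0567) or oil and pathogen 3 (0.0812).

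For single genes in that comparison, log2 fold changes were 4.72 for il8 (SE 1.19), 4.09 for il1b (SE 1.36), 3.84 for mmp9 (SE 1.12), 3.65 for ahrr (SE 1.26), 2.63 for irg1 (SE 0.91) and 1.53 for tiparp (SE 0.62), all at an edgeR adjusted p of 1. Without oil and pathogen 3 the values were 1.55 for il8, 2.02 for il1b, 1.53 for mmp9, 1.35 for irg1, 0.63 for hamp, 3.96 for ahrr and 1.83 for tiparp. Ahrr was higher in each library with both exposures than in each oil library, where it read 1.79, 2.74 and 2.24 CPM. Indicators with a larger p were c7 (3.91, SE 2.85), hamp (2.84, SE 1.80), hmox1 (0.72, SE 0.64), irf1 (0.22, SE 0.59) and lyz (-0.67, SE 2.59). The remaining small p-values were those of the LIM-domain gene csrp2 (2.29, SE 0.61), cldn5b (-2.73, SE 0.78), the phospholipase gene pla2g15 (2.21, SE 0.65) and fstl4, with 3.73 ± 2.61 CPM with oil and 0 reads with both. Here edgeR called 0 genes, with 288 at an unadjusted p under 0.05, DESeq2 called 13 and voom with quality weights 4. The 288 became 86 without oil and pathogen 3, 415 without oil and pathogen 2, 647 with only the 2 groups and 1092 with voom. Without oil 3 edgeR called 1.

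The interaction asked whether the oil effect differed between fish with and without the pathogen. Oxidative phosphorylation genes had a negative interaction in 23 of 23 members (median log2 difference -1.07, camera adjusted p = 5.89e-08) and ribosomal protein genes in 62 of 63 (median -1.22, adjusted p = 3.58e-19), as did phase II genes in 15 of 22 (median -0.63, adjusted p = 0.0162). Pro-inflammatory genes were positive in 17 of 20 (median 1.09, adjusted p = 0.00664) and neutrophil markers in 13 of 17 (median 0.77, adjusted p = 0.0149). Liver (14 of 15 negative, adjusted p = 4.95e-06), acute-phase (16 of 17, 0.00265) and pancreas markers (5 of 5, 0.00265) passed too. With an estimated correlation the adjusted p was 0.70 for 7 of the 8 lists and 0.72 for acute-phase genes, and without pathogen 3 the adjusted p was 0.075 for phase II, 0.261 for pro-inflammatory and neutrophil, 0.959 for acute-phase and 0.0791 for pancreas and liver genes. Single omissions of control 1 (0.0929), pathogen 1 (0.0869), oil 1 (0.0662), oil and pathogen 1 (0.0794) or oil and pathogen 2 (0.0629) also ended the phase II call. Without control 1 the neutrophil list had 0.14 and the pancreas list 0.379, and without oil 3 the neutrophil list had 0.106 and the acute-phase list 0.236. Without both pathogen 1 and pathogen 3, oxidative phosphorylation (0.651), phase II (0.823), neutrophil (0.121), pancreas (0.499) and liver genes (0.211) did not pass, and acute-phase genes pointed up (0.748). The named genes with the smallest p were mnd1 and irg1, with 0 reads in the pathogen libraries, gdpd1, with 0 reads in controls, the metal transporter gene slc39a8 and the carbonyl reductase gene cbr1 (log2 difference -1.94, SE 0.56). Slc39a8 averaged 1.10 ± 0.700 CPM in controls, 3.77 ± 1.96 with oil, 26.6 ± 42.2 with pathogen and 0.305 ± 0.343 with both. Among indicators, mmp9 had 5.74 (SE 1.65), il8 3.61 (SE 1.76), hmox1 0.93 (SE 0.96), irf1 0.73 (SE 0.88), tiparp 0.57 (SE 0.91), ahrr 0.44 (SE 1.82), hamp -0.03 (SE 2.47), c7 -2.0 (SE 4.40) and lyz -3.34 (SE 4.07). Without oil and pathogen 3 mmp9 had 3.43, il8 0.45 and hamp -2.25, and without pathogen 3 hamp had 3.51. Ahrr had -5.47 without control 1, which leaves a control with 0 reads, and lyz had 1.83 without oil 2. Il1b has no difference given, as pathogen libraries had 0 reads. EdgeR called 0 genes at an adjusted p of 1 throughout, with 433 at an unadjusted p under 0.05, DESeq2 called 8 (1 without pathogen 3) and voom with quality weights 0.

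Averaged over fish with and without the pathogen, the oil effect had lower ribosomal protein genes (62 of 63 members, median log2 fold change -0.91, camera adjusted p = 1.74e-39) and oxidative phosphorylation genes (21 of 23, median -0.48, adjusted p = 3.14e-05). Low ribosomal scores came from oil 3 (-0.89), oil and pathogen 1 (-0.87) and oil and pathogen 3 (-1.13), the 3 libraries with the highest TMM factors (1.73, 1.64 and 1.58). The other oil-exposed libraries, at 0.18, 0.10 and -0.06, lay near the controls (0.36 and 0.01), and pathogen 1 scored 1.58. The lower oxidative phosphorylation genes came from the comparison within pathogen-exposed fish: in oil against control 13 of 23 were higher (median 0.10, adjusted p = 0.877). Cell cycle genes were higher in 33 of 43 (median 0.43, adjusted p = 0.000565) and neutrophil markers in 14 of 17 (median 0.48, adjusted p = 0.00498). Smaller calls were pro-inflammatory (16 of 20 higher, 0.0266), heat shock (21 of 31 higher, 0.0298), phase II (15 of 22 lower, 0.0168), pancreas (5 of 5 lower, 0.000565) and liver genes (14 of 15 lower, 0.0278). In oil against control liver genes were instead higher in 14 of 15 (camera adjusted p = 0.134), so the averaged fall came from the comparison within pathogen-exposed fish. Single libraries stood out on the liver list in each. Scores were 2.73 in oil 3 and 7.87 in pathogen 3, against -1.89 to 0.09 in the others. With an estimated correlation the adjusted p was 0.82 to 0.94 for these 9 lists. Without pathogen 3 the pro-inflammatory (0.376), neutrophil (0.0676), phase II (0.0676) and liver (0.899) calls were lost. Phase II genes also had 0.0832 without pathogen 1, 0.0587 without oil 3 and 0.0523 without oil and pathogen 2, and pro-inflammatory genes 0.0503 without oil 2 and 0.178 without oil and pathogen 3. The liver call was lost without control 2 (0.163), oil 1 (0.113), oil 2 (0.0951) or oil and pathogen 2 (0.088), the pancreas call without control 2 (0.0762), and the heat shock call was lost without control 2 (0.435), pathogen 2 (0.635), oil 2 (0.0606) or oil and pathogen 3 (0.248), and with the replicate block (0.0579). Without both pathogen 1 and pathogen 3 the oxidative phosphorylation (0.816), phase II (0.634) and pancreas (0.189) calls were lost, and liver genes pointed up (0.446). Irg1 had 5.94 ± 0.723 CPM with oil against 2.17 ± 2.32 in controls, a difference that did not pass (log2 fold change 1.45, SE 1.07, edgeR adjusted p = 1), and its 6 oil-exposed libraries all lay above the other 5 (edgeR adjusted p = 0.711 for the averaged effect). Gp91phox (log2 fold change 1.38, SE 0.30), pgls (1.43, SE 0.33), lrrc32, with 1 read in the pathogen libraries, and cldn5b (-2.55, SE 0.54) had the same adjusted p, as had mmp9 (3.20, SE 0.89) and il1b. The other indicators had 1.76 for il8 (SE 0.89), 0.71 for ahrr (SE 0.90), 0.47 for hamp (SE 1.29), 0.34 for irf1 (SE 0.44), 0.08 for hmox1 (SE 0.48), -0.05 for lyz (SE 1.95), -0.23 for tiparp (SE 0.46) and -0.64 for c7 (SE 2.28). Without oil and pathogen 3 mmp9 had 2.04, il8 0.18 and hamp -0.62, and without pathogen 3 hamp had 2.27. Of the apoptosis list rps27l passed when adjusted over the list alone (0.044), and the list did not (adjusted p = 0.563). In total 68 genes were higher and 33 lower in every oil-exposed library than in every other, where chance gives 24.6 each way on average (0.216% of genes). Genes vary together and this count was not taken for other splits, so an excess over chance is not shown. By edgeR 0 genes passed, with 782 at an unadjusted p under 0.05, DESeq2 called 23 (2 higher, 21 lower) and voom with quality weights 0. Of the 23430 rows, 22350 had no adjusted p by DESeq2 here, so its adjustment covered far fewer genes than that of edgeR. Without pathogen 3 DESeq2 called 94 (54 higher, 40 lower).

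The averaged pathogen effect had the smallest adjusted p of any contrast, 0.0905. T cell markers were lower in 12 of 13 members (median log2 fold change -0.98, camera adjusted p = 4.37e-05). Pathogen 3 (-2.63) and oil and pathogen 3 (-2.0) stood apart on that list, the other pathogen-exposed libraries scoring 0.08 to 0.42 and the unexposed 0.48 to 0.95. Lower too were pattern recognition genes, in 12 of 15 (median -0.37, adjusted p = 0.0317). Oxidative phosphorylation (23 of 23, median 0.56, adjusted p = 5.72e-08), heat shock (25 of 31, 0.000282), phase II (19 of 22, 0.000801), erythroid (18 of 22, 0.000963) and acute-phase genes (14 of 17, 0.0317) were higher. With an estimated correlation the adjusted p was 0.81 for acute-phase genes and 0.74 for the other 6. Without pathogen 3 the acute-phase list pointed down (0.72) and the pattern recognition list had 0.326, and without pathogen 1 the erythroid list had 0.0701. The pattern recognition call was also lost without control 1 (0.113) or oil and pathogen 3 (0.0635), and the acute-phase call without control 1 (0.172), oil 1 (0.125), oil 2 (0.0637) or oil and pathogen 3 (0.087), and with the block (0.269). Without both pathogen 1 and pathogen 3 the oxidative phosphorylation (0.162), heat shock (0.51), phase II (0.145) and pattern recognition (0.248) calls were lost, and acute-phase genes pointed down (0.145). Of the 6 aryl hydrocarbon receptor and phase I genes tested, ahrr passed when adjusted over the list alone (0.0327), but the list did not pass (adjusted p = 0.45). Its log2 fold change was 3.43 (SE 0.99, edgeR adjusted p = 0.824 over all genes), that of tiparp 1.25 (SE 0.47) and that of il8 2.91 (SE 0.91). The other indicators had 4.91 for c7 (SE 2.37), 2.86 for hamp (SE 1.42), 1.00 for lyz (SE 1.98), 0.97 for mmp9 (SE 0.84), 0.26 for hmox1 (SE 0.49) and -0.14 for irf1 (SE 0.44), at adjusted p-values from 0.824 to 0.964. Without oil and pathogen 3 il8 had 1.33, hamp 1.75 and mmp9 -0.18, and without pathogen 3 hamp had 1.07. For il1b no fold is given here, as pathogen libraries had 0 reads. The fitted values printed under the processing settings depend on how each fit treats those 0 reads. Pathogen 3 had 0 reads of ahrr, which allows up to 2.19 CPM; without that library ahrr had 3.69 (adjusted p = 0.164) and tiparp 1.49 (adjusted p = 0.364), and DESeq2 without it called both (adjusted p = 9.44e-07 and 0.0069).

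The smallest p-values for the averaged pathogen effect belonged to loci that the files pair with no gene name. LOC101074617 averaged 4.28 ± 2.90 and 2.81 ± 1.19 CPM in the pathogen and combined groups against 44.7 ± 16.9 and 30.0 ± 13.4 in controls and oil (log2 fold change -3.39, SE 0.46, edgeR adjusted p = 0.0905). LOC101062231 had -2.49 (SE 0.42, adjusted p = 0.248), LOC101070953 2.42 (SE 0.36, adjusted p = 0.0935) and LOC101074542 6.42 (SE 1.10, adjusted p = 0.40). The last averaged 243.1 ± 62.7 and 160.7 ± 80.7 CPM in the pathogen and combined groups against 0.378 ± 0.0339 in controls and 13.1 ± 20.4 with oil, where oil 3 held 36.6 CPM. Among genes with a symbol these were csrp2 (2.25, SE 0.47), the growth factor gene bmp7 (1.26, SE 0.32), the mitochondrial import gene timm44 (1.65, SE 0.43), raver2 (-3.11, SE 0.76) and rnf144a (-1.38, SE 0.36), at adjusted p-values of 0.69 for csrp2 and 0.824 for the others. In this contrast 15 genes were higher and 63 lower in every pathogen-exposed library than in every other, where chance gives 24.6 each way on average. As for oil, other splits were not counted in this way, so an excess over chance is not shown. EdgeR called 0 genes, with 605 at an unadjusted p under 0.05, DESeq2 called 9 (31 without pathogen 3) and voom with quality weights 4. Without pathogen 3 edgeR called 4 (LOC101074617, LOC101062231, LOC101070953 and ttc34, each at adjusted p = 0.0414), and without oil 3 it called 2.

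The lists that passed in no contrast had their smallest camera adjusted p at 0.299 for interferon response, 0.534 for antigen presentation, 0.528 for apoptosis, 0.205 for thrombocyte, 0.0559 for muscle, 0.137 for circadian, 0.05 for sterol and fatty acid synthesis, 0.45 for aryl hydrocarbon receptor and 0.0872 for glucocorticoid-responsive genes. In all, 57 of 184 list tests passed with the preset correlation, and 0 with an estimated correlation.

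Fold changes of comparisons that share no library were set against each other across the 11374 genes, which are not independent replicates. The oil effect without pathogen and that with pathogen had a Pearson correlation of -0.14 and a Spearman correlation of 0.12, and 55.2% of genes had the same sign. For the pathogen effect without and with oil these were -0.27, 0.08 and 54.4%. Without pathogen 3 the Pearson correlations were 0.21 and 0.22.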

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

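All tests of explanations in this part were chosen after the results they measure had been seen, the test of an acute-phase response replaced an earlier version with the same verdict, and the marker share of pathogen 3 replaced one limited to markers with reads in that library, which had been read as support for other tissue.

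The oil effect differed between fish with and without the pathogen, by the camera test of the interaction with a preset correlation, in 8 gene lists. The adjusted p was 3.58e-19 for ribosomal protein, 5.89e-08 for oxidative phosphorylation, 4.95e-06 for liver, 0.00265 for acute-phase, 0.00265 for exocrine pancreas, 0.00664 for pro-inflammatory, 0.0149 for neutrophil and macrophage and 0.0162 for phase II genes. With an estimated correlation 0 of the 8 passed, at adjusted p-values of 0.70 to 0.72, so these differences rest on the preset value. Most also rest on pathogen 3. Without it camera called 3 lists, and the liver, acute-phase, pancreas, pro-inflammatory, neutrophil and phase II calls were lost. For slc39a8 and tldc1 every oil library lay above the controls while every library with both exposures lay below the pathogen libraries. The interaction log2 fold change was -7.96 for slc39a8, whose pathogen mean was set by 75.3 CPM in pathogen 3, and -2.81 for tldc1. The edgeR adjusted p was 1 for both.

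Of the 22 liver and pancreas markers with at least 10 reads in some library, 21 had their highest level in pathogen 3, or 95.5%, with and without the normalization factor. Liver and pancreas tissue in this sample is a candidate explanation, but this share restates the pattern and cannot support it, so it stays open. An acute-phase response of the spleen would raise acute-phase genes without digestive enzymes, and was argued against as the whole cause by pancreas markers at 2.80% of counts, against at most 0.836% in any other library. Such a response as part of the cause stays open.

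The receptor repressor ahrr was high in pathogen 1, pathogen 2 and the 3 libraries with both exposures, and low in control, oil and pathogen 3 libraries. Reads from liver or pancreas were argued against, since these markers took at most 0.242% of counts in the 5 high libraries and 0.868% in control 2, where ahrr had 0 reads. An exchange of the oil and pathogen labels as whole groups, in which ahrr would follow oil, cannot be told apart from the labels as given. By camera the pro-inflammatory list did not pass in the libraries labelled oil against control (adjusted p = 0.888). Nor did it pass in those labelled pathogen against control (0.541, with 12 of 20 members lower), so this list favours neither labelling. Irg1 and gp91phox were higher in the libraries labelled oil than in the libraries labelled pathogen. Il8 was higher in each of the 6 pathogen-labelled libraries than in each other library only after scaling by the TMM factors, since in CPM without a factor pathogen 1 (0.51) and pathogen 3 (0.46) were the lowest of the 11 libraries, and with 2 to 12 reads in 5 of the 6 it does not exclude the exchange. An effect of pathogen exposure on ahrr also stays open, at an edgeR adjusted p of 0.164 without pathogen 3.

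The genes il1b, il8, mmp9 and irg1 were highest in oil and pathogen 3. Reads from liver were argued against by a liver share of 0.0057% of counts. Normalization of a shallow library was argued against, because il8 in CPM without a factor was 26.3 times that of the next highest library. A larger share of neutrophils may contribute: the neutrophil and macrophage score of this library was 0.44 above the mean of the other libraries of the group, a difference between single libraries that decides nothing.

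The libraries were regrouped to ask how often other splits give results as large. The real split is included in each number of splits, so 1 of 10 means that no other split was as large. For both exposures against pathogen, 1509 genes had an unadjusted p under 0.05 and the highest other split gave 1320, with 1 of 10 splits as large. DESeq2 called 356 genes there against at most 187 in other splits, 1 of 10 as large, and each of the 9 other splits called genes. For both against oil the count was 288 against a highest other of 420, with 2 of 10 as large. In both, 10 splits are too few for a share under 0.05. For the average oil effect, 782 genes against a highest other of 1245, and for the average pathogen effect 605 against 2079, chance could not be excluded, with 10 and 43 of 100 splits as large. List calls did not exceed other splits. They were as many in 8 of 10 splits for both against pathogen (8 lists, highest other 13), in 9 of 10 for both against oil (6, highest other 11), in 46 of 100 for the average oil effect (9, highest other 13) and in 75 of 100 for the average pathogen effect (7, highest other 15). Which libraries the split with 2079 genes put together was not examined.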

How the results depend on the processing

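Voom with quality weights, leaving out pathogen 1 and pathogen 3 together, DESeq2 without pathogen 3, the list tests without single libraries and the correlations without pathogen 3 were chosen after the data were seen, the rest before; a comparison with uniquely mapped reads, also set before, was not run, as the files hold 1 kind of count. EdgeR called 0 genes in each comparison, with 53 to 1509 at an unadjusted p under 0.05 with TMM and 53 to 1535 with DESeq2 size factors. These unadjusted counts moved with single libraries. Without oil and pathogen 3 and without pathogen 2 they were 475 and 1644 for the average oil effect, 366 and 1659 for the average pathogen effect, and 233 and 1288 for the interaction. For both against control the count was 173 without oil and pathogen 3. The other counts, whose cause was not tested, were as follows. DESeq2 called 22 for pathogen against control, 12 for both against control, 356 for both against pathogen, 13 for both against oil, 8 for the interaction, 23 for the average oil and 9 for the average pathogen effect, and without pathogen 3 it called 12, 45, 271, 9, 1, 94 and 31. Voom called 4 for both against control, 4 for both against oil and 4 for the average pathogen effect. Without pathogen 1 and pathogen 3 edgeR called 3 for both against control and 2 for both against oil, with only the 2 groups 2 for both against control, and without a filter 1 for the average pathogen effect. Leaving out 1 library at a time gave 0 to 4 for the average pathogen effect, 0 to 1 for pathogen against control, both against pathogen and both against oil, and 0 to 0 for the others. With the replicate number as a block edgeR called 3 for both against pathogen and 3 for the average oil effect. Whether the numbers pair libraries is not settled. Of 15 pairs with the same number, which ran from -0.19 to 0.40, 4 correlated above 0.1, and 5 of the 11 libraries correlated best with their own number. The 5 genes called with the block, among them ftcd, pah, uroc1 and cfi, were all lower and all highest in pathogen 3, with 602 to 1171 reads there and 0 to 2 in pathogen 1 and pathogen 2. Of 57 list calls, DESeq2 size factors kept 57 and the block 51, with pathogen against control going from 10 (7 higher, 3 lower) to 6 (6 higher, 0 lower). An estimated correlation gave 0 in each of the 8 comparisons, and fry gave 0 in its directional and its mixed test. Without pathogen 1 and pathogen 3, which leaves 1 pathogen library assumed to vary like the others, 28 of the 57 calls were kept, 22 were lost and 7 pointed the other way. The lists called higher and lower went from 2 and 6 to 4 and 2 for both against pathogen, from 4 and 5 to 5 and 2 for the average oil effect and from 5 and 2 to 1 and 3 for the average pathogen effect. In that setting the lists called were 1 for pathogen against control, 3 for the interaction and 4 for the average pathogen effect. Leaving out single libraries gave 3 to 6 for oil against control, 4 to 13 for pathogen against control, 5 to 8 for both against control, 6 to 11 for both against pathogen, 5 to 8 for both against oil, 3 to 12 for the interaction, 6 to 11 for the average oil effect and 6 to 11 for the average pathogen effect. The correlation of oil effects (-0.14) was -0.26 for genes with a mean log2 CPM of at least 3 and 0.21 without pathogen 3, and that of pathogen effects (-0.27) was -0.49 and 0.22. Indicator log2 fold changes that changed sign, none past edgeR's threshold, follow, in the order oil, pathogen and both against control, both against pathogen, both against oil, interaction, average oil and average pathogen effect. Without a filter they were hamp 0.04 for the interaction, lyz 0.01 for average oil. With DESeq2 they were il1b 0.13 for average pathogen. With DESeq2 and pathogen 3 left out they were ahrr -0.11 for the interaction, c7 -3.34 for pathogen against control, 7.66 for both against pathogen, 7.42 for the interaction and 3.96 for average oil, hamp -0.65 for pathogen against control and 3.55 for the interaction. It gave hmox1 0.20 for pathogen against control and -0.10 for average oil, irf1 0.09 for average pathogen, lyz 0.49 for average oil. It gave tiparp -0.41 for both against pathogen. With the block they were c7 -2.99 for oil against control, -0.91 for both against control and 1.83 for the interaction, hamp 0.90 for the interaction, il1b -0.88 for oil against control. It gave irf1 0.41 for oil against control, lyz 0.71 for both against oil, mmp9 -0.26 for oil against control. It gave tiparp 0.02 for oil against control and 0.14 for average oil. Without both pathogen 1 and pathogen 3 they were ahrr -0.25 for both against pathogen and -0.73 for the interaction, c7 -4.43 for pathogen against control, 8.71 for both against pathogen, 8.34 for the interaction, 4.54 for average oil and -0.26 for average pathogen, hamp -1.29 for pathogen against control and 4.11 for the interaction. It gave hmox1 0.13 for pathogen against control and -0.08 for average oil, lyz -6.56 for pathogen against control, 7.52 for both against pathogen, 5.86 for the interaction, 4.59 for average oil and -3.63 for average pathogen, tiparp -0.80 for both against pathogen and -0.29 for the interaction. With voom they were ahrr -0.75 for the interaction, c7 0.14 for both against pathogen, -0.46 for both against oil, 0.41 for average oil and -0.19 for average pathogen, hamp -0.02 for pathogen against control and 1.13 for the interaction. It gave hmox1 -0.28 for both against control, -0.25 for both against pathogen, -0.08 for both against oil, -0.06 for the interaction, -0.22 for average oil and -0.05 for average pathogen, il1b -0.08 for oil against control and 0.27 for average pathogen, il8 0.01 for oil against control. It gave lyz 0.13 for both against pathogen, 1.85 for average oil and -1.29 for average pathogen. Ahrr, with single libraries left out, ranged from -0.49 to 6.43 for oil against control and -5.47 to 2.09 for the interaction. C7, with single libraries left out, ranged from -0.65 to 4.63 for oil against control and -1.13 to 1.5 for average oil. Hamp, with single libraries left out, ranged from -1.16 to 1.60 for oil against control, -0.68 to 3.95 for pathogen against control, -1.74 to 4.02 for both against pathogen, -2.25 to 3.51 for the interaction and -0.62 to 2.27 for average oil. Hmox1, with single libraries left out, ranged from -0.76 to 0.16 for oil against control, -0.61 to 0.32 for pathogen against control, -0.65 to 0.89 for both against control, -0.45 to 0.92 for both against pathogen, -0.27 to 1.09 for both against oil, -0.07 to 1.33 for the interaction, -0.41 to 0.36 for average oil and -0.24 to 0.52 for average pathogen. Il1b, with single libraries left out, ranged from -0.61 to 1.63 for oil against control and -1.68 to 0.12 for average pathogen. Il8, with single libraries left out, ranged from -0.16 to 0.09 for oil against control. Irf1, with single libraries left out, ranged from -0.33 to 0.15 for oil against control, -0.21 to 0.51 for both against control, -0.19 to 0.54 for both against oil and -0.40 to 0.09 for average pathogen. Lyz, with single libraries left out, ranged from -3.56 to 11.33 for oil against control, -0.04 to 10.65 for both against control, -1.34 to 4.51 for both against oil, -13.03 to 1.83 for the interaction and -2.64 to 4.82 for average oil. Mmp9, with single libraries left out, ranged from -0.24 to 1.27 for oil against control and -0.18 to 1.44 for average pathogen. Tiparp, with single libraries left out, ranged from -0.40 to 0.86 for both against pathogen and -0.46 to 0.17 for average oil. Fitted values of il1b and irg1 with all pathogen libraries at 0 depend on the prior count. The sign changes have causes that were not tested. The 33 further fold changes of irg1, gp91phox and the 4 numbered loci, not printed for every comparison, changed sign in 19 of 487 values under alternatives and passed the threshold in 28. Of the printed fold changes, DESeq2 put 15 past the threshold, DESeq2 without pathogen 3 put 30, voom 3, edgeR without pathogen 3 put 3, without oil 3 put 2 and without a filter 1. At these depths the 0 reads of irg1 in the pathogen libraries allow 0.625 to 2.19 CPM per library.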

Other observations

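No hypothesis was tested on the following values. On log2 CPM, the first 3 principal components held 39.8%, 23.7% and 12.4% of the variance. The first component set pathogen 3 apart from the other 10 libraries, the next pathogen 1, and the third oil and pathogen 3.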
